A study of Mus musculus with 23 samples.

How the data were processed

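The series holds 5C data (chromosome conformation capture carbon copy, in which primers at restriction sites of a chosen region turn ligated contacts into a library) from mouse. Nuclei were fixed with formaldehyde, digested with HindIII, ligated and sequenced, per the labels. The 23 samples give 21 libraries, because each of the 2 D700 embryo libraries merges 2 technical replicates. The region is 28.317 to 29.997 Mb on chromosome 5 of the mm9 build, named in the bin names.

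3 kinds of matrix were used. The deposited binned matrices hold a contact value, a signal without a stated normalization, for each pair of 80 bins of 21 kb. Their values are not whole numbers, and in the full-size libraries about 34 percent of pairs equal the value of the neighbouring bin (34.0 percent in anterior limb bud replicate 1). The reason is not given in the sources used here, and single pairs are therefore not independent. A second set of deposited matrices for the 14 embryonic stem cell (ESC) libraries holds a ratio, observed over expected. Division of the contact values by this ratio gave 1 expected value per bin separation, with a largest relative spread of 3.58e-08. The deposited fragment matrices of the 4 limb bud libraries hold counts, whole numbers per pair of 343 HindIII fragments. The aligner and the software of the authors are not given in the sources used here. 19 matrices in which replicates are added together were not used here.

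Bins 25, 29 and 64 have no value in any library. The D700 matrices lack bins 27 to 58, from 28.884 to 29.556 Mb, a stretch of 672 kb that was read as the deletion. In both D35 libraries bin 65 (29.682 to 29.703 Mb) is at 0 with 59 bins, against at most 2 bins in the other libraries, and it was read as lying in the D35 deletion.

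Groups follow the sample titles. They are wild type ESC (2 libraries), ESC lines DCTCF1 to DCTCF5 and D35 (2 each), E11.5 anterior and posterior limb bud (2 each), E11.5 D700 embryos (2) and the E11.5 embryo body (1). The position of each deleted site of the DCTCF lines is not given in the sources used here. The run label of DCTCF2 replicate 2 carries a technical mark although its title says biological replicate, and it was treated as biological. Run years come from the labels. Wild type and DCTCF1 have 1 library each from 2015 and 2016, DCTCF2 and DCTCF3 are from 2015, DCTCF4 and DCTCF5 from 2016, D35 from 2017, the limb buds and D700 from 2015 and the embryo body from 2014.

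The tests, the groups and the rule for naming results were fixed before the data were examined. Bin pairs at least 2 bins apart and above 0 in at least 50 percent of the libraries were scaled to one total per library. They were then compared by limma 3.58.1 in R 4.3.3 on log2(value + pseudocount). The pseudocount was the 5th percentile of values above 0, which was 4.56 for the DCTCF lines, 4.54 for D35, 5.34 for the limb bud parts, 8.56 for D700 and 5.25 for ESC against limb bud. Benjamini-Hochberg adjustment ran over the pairs of each comparison, with 0.05 as the threshold. All ESC comparisons come from 1 fit of 14 libraries. The D700 comparison also used the limb bud libraries to estimate the spread, so the lone body library is assumed to vary like the other groups. Pairs of bin 65 were left out for D35.

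The insulation value of a bin is log2 of the mean contact value between the 5 bins before it and the 5 bins after it, minus the mean of these values over the library. A low value marks a boundary, and a rise means more contact across the bin relative to the rest of the region. It does not use the bin's own contacts, so a bin without contact values can have one. Windows of neighbouring bins share contact pairs, so calls at adjacent bins are not independent. Profiles were compared by limma. A window needed a value in at least 50 percent of its pairs, a limit set after the data were seen. For D700 the deleted bins were left out of every library. Bin 65 was left out of all ESC libraries for D35 only. This choice was also made after the data were seen: profiles were first computed without bin 65 for all lines, and the version with bin 65 was then taken for DCTCF1 to DCTCF5 because it follows the plan. Bins of DCTCF1 to DCTCF5 whose call differs between the versions are given beside the results.

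Boundaries are local minima of a mean profile with a prominence of at least 0.2. Those for the ESC lines were found in the embryo libraries, and those for the embryo comparisons in wild type ESC. Mean contact values within and between the resulting domains were compared by limma. For the comparison of wild type ESC with limb bud the boundaries come from one of the groups compared. A coarser map with only the boundaries of prominence above 1 was added after the data were seen. Libraries were compared by Pearson correlation after the mean at each separation was removed, with a one-sided permutation test (100000 resamples). Fragment counts were compared by edgeR 4.0.16 (quasi-likelihood test, pairs above 0 in at least 2 libraries), with DESeq2 1.42.0 as an alternative.

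Named are, per comparison, up to 5 of the highest and 5 of the lowest called pairs whose replicates do not overlap, up to 3 of the highest and 3 of the lowest called insulation values, the domain blocks, and the 3 pairs of smallest p where none is called. A planned test of fixed pairs of promoters and of the limb enhancer was not run, because no gene annotation on mm9 was used here, and so bins are given by coordinates only.

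The depth of the binned matrices is unknown. Their contact values sum to between 62111.9 (embryo body) and 106303 (DCTCF4 replicate 1), and these sums are not read counts. Fragment count totals run from 749738 to 1400830. Groups hold 1 or 2 libraries, and limma shares the spread over bins and groups.

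The fits were tested on simulated data with the spread of the real libraries and 200 changed pairs. For D35 against wild type, 23.9 percent of changes of 0.5 on the log2 scale, 95.5 percent of changes of 1 and 100 percent of changes of 2 were recovered with 6 false calls. For D700 the shares were 17.9, 83.6 and 100 percent, and for the limb bud parts 14.9, 92.5 and 100 percent. The edgeR fit of fragment counts recovered 0 of 67, 0 of 67 and 0 of 66 changes of 1, 2 and 3 at the estimated dispersion of 1.11. At a dispersion of 0.1 it recovered 0 of 67, 18 of 67 and 55 of 66. DESeq2 made 98 false calls at the estimated dispersion.

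Alternatives were other pseudocounts, filters, scalings, separations and windows, the replicate number as a block and the run year as a covariate. Further ones were the other deletion lines as control and leaving out each replicate. For DCTCF1 to DCTCF5 the other deletion lines include D35, and in the tests of bin pairs and insulation bin 65 was kept in that control. Added after the data were seen were 1 feature per distinct value (1439 distinct values among 2853 pairs in the ESC libraries), other handling of bins 65 and 66 (also on the coarser map), scaling of D700 within the flanks, the coarser map, the replicate block for the domain blocks of the limb bud, and thinning of counts. Replicate numbers were checked for pairing by correlating the differences between replicates 1 and 2. These correlations ran from -0.11 to 0.10 over 21 pairs of ESC groups and were -0.03 for the limb bud parts, so the numbers did not pair the ESC libraries in the values. In the limb bud the replicate number is also the sequencing day, and a fit with the replicate block is given beside that comparison.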

Results

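The libraries cover 28.317 to 29.997 Mb on chromosome 5 (mm9), the region around Shh, which encodes the secreted signal Sonic hedgehog and gives the 5C fragments their names. They come from E14 mouse ESC (wild type, 5 lines named DCTCF1 to DCTCF5 and a deletion line named D35) and from E11.5 mouse embryos (anterior and posterior limb bud, the embryo body and embryos with the deletion D700). Each group has 2 libraries except the embryo body, which has 1. CTCF is a DNA-binding protein found at many domain boundaries, and the comparisons ask whether contacts of the region differ when such sites or larger stretches are deleted, and between tissues. Contact values have no stated unit. Their totals per library run from 62111.9 to 106303, and the sequencing depth behind them is unknown.

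Wild type ESC showed 3 domains separated by 2 deep minima of contact. The left boundary lay at bin 21 (28.758 to 28.779 Mb), with an insulation value of -1.15 ± 0.29 (SD, n = 2) and a prominence of 1.78. The right boundary lay at bin 65 (29.682 to 29.703 Mb), with -0.77 ± 0.08 (SD, n = 2) and a prominence of 1.31. The central domain between them (28.779 to 29.682 Mb) had a mean contact value of 24.8 ± 1.35 (SD, n = 2). Contacts between the left (28.317 to 28.758 Mb) and the central domain averaged 9.45 ± 0.56, and those between the central and the right domain (29.703 to 29.997 Mb) averaged 8.24 ± 0.28 (SD, n = 2 each). The mean profile of the limb bud and body libraries had its most prominent minima at the same bins, with prominences of 1.76 at bin 21 and 1.06 at bin 65. In the single embryo body library the prominence at bin 65 was 0.44, below the 0.53 at bin 32 (28.989 to 29.010 Mb).

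**Figure D1:**
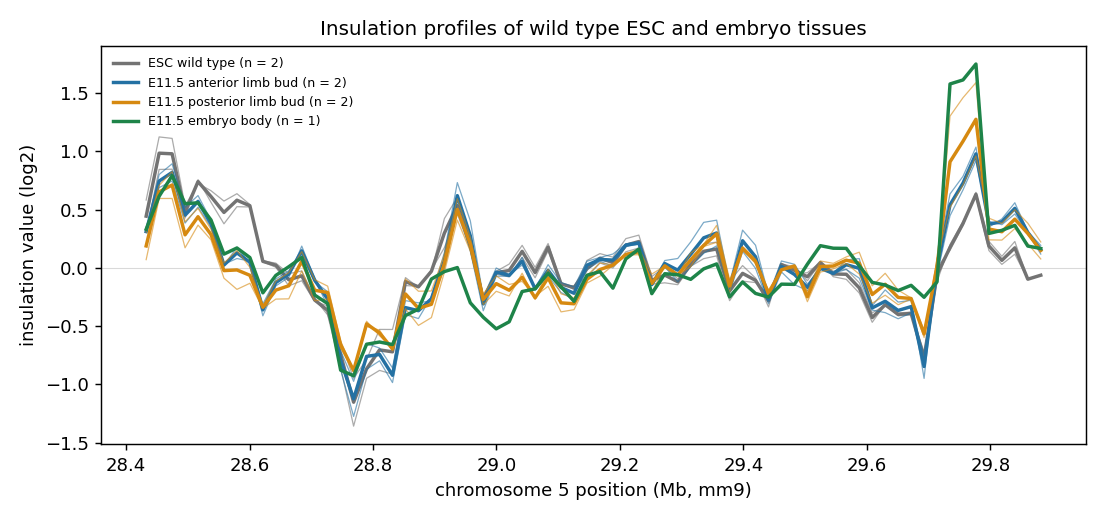
Insulation value (log2, y axis) along chromosome 5 (Mb, x axis) for wild type ESC and 3 embryo tissues, with thin lines for replicates and thick lines for means. The minima at bin 21 and bin 65 appear in each tissue. The embryo body has the shallowest one at bin 65, with a prominence of 0.44, below the 0.53 at its bin 32.

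On average, ESC libraries of the same line resembled each other more than libraries of different lines. The mean correlation within lines was 0.859, against 0.782 ± 0.059 (SD) between lines, across bin pairs that are not independent (one-sided permutation test, p = 2e-05). Both replicates share a run year in all lines but wild type and DCTCF1, so line and run year are partly confounded here. DCTCF1 replicates were closest, with 0.931, and DCTCF4 replicates least close, with 0.782. DCTCF5 replicates correlated at 0.814 and with wild type at 0.837 on average, and DCTCF3 replicates at 0.843 and with wild type at 0.836. Among embryo libraries the posterior limb bud replicates correlated at 0.644 and the anterior ones at 0.844.

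In DCTCF1 contact rose across the bins just left of the left boundary. Contact across bin 20 (28.737 to 28.758 Mb) rose by 0.36 ± 0.10 (SE) on the log2 scale and across bin 19 (28.716 to 28.737 Mb) by 0.35 ± 0.07, relative to wild type (n = 2 each, adjusted p 0.036 and 0.0079). The insulation value at bin 19 was -0.02 in DCTCF1 and -0.37 in wild type. The boundary bin 21 itself changed by 0.28 and did not pass (adjusted p 0.104), and bin 22 was at -0.93 in DCTCF1 and -0.87 in wild type. Contact across bin 60 (29.577 to 29.598 Mb) in the right part of the central domain rose by 0.27 ± 0.07 (adjusted p 0.036). On the coarser map the contact value between the left and the central domain was 11.4 ± 0.03 against 9.45 ± 0.56 in wild type (SD, n = 2 each), a log2 change of 0.27 ± 0.09 (SE, adjusted p 0.023). Contact decayed less steeply over distance in DCTCF1, with a mean slope of -0.61 against -0.70 in wild type, and as observed over expected the change of this block was 0.16 (adjusted p 0.024).

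Of 70 bins tested in DCTCF1, 6 had a higher and 0 a lower insulation value, and in both DCTCF1 libraries each named bin lay above both wild type libraries. Within the earlier and the later run year, with 1 library per group in each, bin 19 changed by 0.29 and 0.40, bin 20 by 0.25 and 0.48 and bin 60 by 0.32 and 0.22, and the left to central block by 0.22 and 0.33. With limma, 0 of 2853 single bin pairs passed, with 218 at an unadjusted p under 0.05. The 3 pairs of smallest p were bin 21 with bin 32 (-0.72), bin 50 with bin 59 (-1.41) and bin 21 with bin 60 (-0.70), each at an adjusted p of 0.149. None of 44 domain blocks passed, with 9 at an unadjusted p under 0.05, while 5 passed with boundaries from wild type ESC. The insulation calls were lost with a window of 3 bins, where the smallest adjusted p was 0.060, bin 20 also with the profile divided by its SD (0.072) and bin 60 with the other deletion lines as control (0.12, adjusted p 0.067). They fell to 0 without DCTCF1 replicate 1, DCTCF1 replicate 2 or wild type replicate 2 and to 3 without wild type replicate 1. Without these 3 in turn the adjusted p was 0.187, 0.167 and 0.177 at bin 20, 0.076, 0.164 and 0.056 at bin 19 and 0.187, 0.167 and 0.056 at bin 60, which also had 0.163 without wild type replicate 1. With the replicate block the left to central block had an adjusted p of 0.054, and it had 0.135 without DCTCF1 replicate 1, 0.119 without DCTCF1 replicate 2 and 0.247 without wild type replicate 2. When bin 65 was left out, bin 66 changed by 0.28 (adjusted p 0.041) instead of -0.11 (adjusted p 0.271), and bins 60 and 61 lost the call (0.23 and 0.21, adjusted p 0.061 and 0.075).

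In DCTCF2 contact changed across bins inside the central and the left domain and at the right boundary. Contact across bins 44 (29.241 to 29.262 Mb), 43 (29.220 to 29.241 Mb) and 50 (29.367 to 29.388 Mb) rose by 0.41 ± 0.07, 0.37 ± 0.07 and 0.36 ± 0.08 (SE, n = 2 each, adjusted p 0.0011, 0.0018 and 0.0067). It fell by 0.31 ± 0.09 at the right boundary, bin 65 (adjusted p 0.019), by 0.30 ± 0.07 at bin 15 (28.632 to 28.653 Mb, adjusted p 0.0073) and by 0.29 ± 0.09 at bin 5 (28.422 to 28.443 Mb, adjusted p 0.025). Contacts within the domain from 29.262 to 29.367 Mb had a value of 68.04 ± 2.65 against 45.8 ± 2.90 in wild type (SD, n = 2 each), a log2 change of 0.57 ± 0.11 (SE, adjusted p 0.0027). Contacts between 29.451 to 29.682 Mb and the right domain were 9.56 ± 0.47 against 11.4 ± 0.23, a log2 change of -0.26 ± 0.08 (adjusted p 0.036).

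On the coarser map nothing passed in DCTCF2 in the main fit: the change was 0.10 within the central domain (adjusted p 0.444), -0.21 between the central and the right domain (0.140) and -0.03 within the left domain (0.733). The central to right block passed with the other deletion lines as control (-0.30, adjusted p 6.3e-04), and the right domain, at -0.05 in the main fit, as observed over expected (-0.16, adjusted p 0.0049). In the central to right block these other lines lie above wild type themselves, by 0.01 (DCTCF3) to 0.19 (D35), which adds to the -0.30. Insulation was higher at 8 and lower at 8 of 70 bins, and 4 of 44 domain blocks were higher and 4 lower. These block calls depend on the boundaries used, since 0 blocks passed with boundaries from wild type ESC. The 4 higher blocks all lay within 28.989 to 29.430 Mb. The 4 lower blocks joined 29.388 to 29.430 Mb with the left domain on either side of bin 14 and with the right domain, and 29.451 to 29.682 Mb with the right domain. Against the wild type library of the same run year, the named bins changed by 0.45, 0.43, 0.44, -0.36, -0.28 and -0.43 in the order above. Of 2853 bin pairs, 266 had an unadjusted p under 0.05 and a single one passed, bin 4 with bin 71 (starting at 28.401 and 29.808 Mb). It was at 3.89 ± 0.81 against 25.2 ± 3.17 (SD, n = 2 each), a log2 change of -1.82 ± 0.27 (SE, adjusted p 0.0488). DCTCF4 was also low there against the same wild type libraries (2.93 ± 4.14). With the other deletion lines as control, DCTCF4 among them, bin 4 with bin 71 was not among the 14 higher and 1 lower called pairs. That pair missed the threshold without any 1 of DCTCF2 replicate 1 (0.104), DCTCF2 replicate 2 (0.466), wild type replicate 1 (0.342) and wild type replicate 2 (0.120). Called bins numbered 8 without DCTCF2 replicate 1, 4 without DCTCF2 replicate 2 and 3 without wild type replicate 1, and called blocks 4, 1 and 0, with 3 blocks without wild type replicate 2. The adjusted p was 0.064 at bin 50 without wild type replicate 1, 0.060 at bin 15 without DCTCF2 replicate 2, 0.200 and 0.158 at bin 65 without DCTCF2 replicate 1 or wild type replicate 1, and 0.142, 0.076 and 0.338 at bin 5 without DCTCF2 replicate 1, DCTCF2 replicate 2 or wild type replicate 1, where its change was -0.15. With a window of 3 bins all named bins but bin 65 missed the threshold: bins 44, 43 and 50 changed by 0.28, 0.20 and 0.36 (adjusted p 0.058, 0.105 and 0.058) and bins 15 and 5 by -0.30 and -0.32 (0.058 each). Bin 15 also missed it with a window of 8 bins (0.090), bin 65 with the profile divided by its SD (0.135) and bin 5 with the other deletion lines as control (0.114). With bin 65 left out, bins 63 and 64 changed by -0.34 and -0.33 (adjusted p 0.012 each) instead of -0.03 and -0.02, which did not pass, and bin 30 gained the call (adjusted p 0.037 instead of 0.058).

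In DCTCF3 the left boundary was deeper and contact rose across some bins inside the central domain. The insulation value at bin 21 (28.758 to 28.779 Mb) was -1.55 in DCTCF3 and -1.15 ± 0.29 in wild type, a change of -0.40 ± 0.10 (SE, n = 2 each, adjusted p 0.024). Contact across bins 49 (29.346 to 29.367 Mb), 43 and 45 (29.262 to 29.283 Mb) rose by 0.32 ± 0.08, 0.31 ± 0.07 and 0.31 ± 0.09 (adjusted p 0.024, 0.013 and 0.032). Contact across bin 74 (29.871 to 29.892 Mb) in the right domain fell by 0.22 ± 0.06 (adjusted p 0.037).

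Insulation was higher at 6 and lower at 2 of 70 bins in DCTCF3, and bin 51 lost the call with bin 65 left out (adjusted p 0.051 instead of 0.049). The change within the whole central domain was 0.09 and did not pass (adjusted p 0.546). As observed over expected the left and the right domain passed (-0.12 and -0.11, adjusted p 0.048 each), against -0.11 and -0.09 in the main fit, which did not pass. Against the wild type library of the same run year, which is replicate 1, bin 21 changed by -0.60 and bin 74 by -0.22. Bins 49, 43 and 45 changed by 0.38, 0.37 and 0.37. At bin 21 that library was at -0.95, and wild type replicate 2 was at -1.36. limma called 0 of 2853 bin pairs, with 201 at an unadjusted p under 0.05, and 0 of 44 domain blocks, with 5 at an unadjusted p under 0.05. The 3 pairs of smallest p were bin 18 with bin 67 (-1.01, adjusted p 0.136), bin 8 with bin 13 (-0.89, adjusted p 0.136) and bin 67 with bin 75 (-0.84, adjusted p 0.163). Called bins numbered 0 without DCTCF3 replicate 2, 0 without wild type replicate 1 and 17 without wild type replicate 2, and bin 21 changed by -0.19 (adjusted p 0.318) without wild type replicate 1. Without DCTCF3 replicate 1 bin 21 had an adjusted p of 0.059, and without wild type replicate 2 bin 74 had 0.053. Without DCTCF3 replicate 2 the adjusted p of the named bins was from 0.215 to 0.268. Without wild type replicate 2, 1 block passed. With a window of 3 bins the change was 0.17 at bin 43, 0.30 at bin 45 and -0.13 at bin 74, none of which passed (adjusted p 0.220, 0.071 and 0.331), and with a window of 8 bins bin 21 missed the threshold (-0.22, adjusted p 0.117). All 5 named bins missed it with the profile divided by its SD (0.068 to 0.169), and bin 74 with the run year as a covariate (0.068).

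In DCTCF4 contact fell across bins inside the left domain and rose across bin 66 next to the right boundary. Contact across bins 5 (28.422 to 28.443 Mb), 11 (28.548 to 28.569 Mb) and 7 (28.464 to 28.485 Mb) fell by 0.55 ± 0.09, 0.39 ± 0.07 and 0.35 ± 0.09 (SE, n = 2 each, adjusted p 4.2e-04, 0.0010 and 0.0083). Contacts between 28.317 to 28.611 Mb and 28.632 to 28.758 Mb had a value of 25.9 ± 0.79 against 33.5 ± 1.02 in wild type (SD, n = 2 each), a log2 change of -0.37 ± 0.08 (SE, adjusted p 0.011). This call depends on the boundaries used, since no block passed with boundaries from wild type ESC or with those of prominence 0.1. Contact across bin 66 (29.703 to 29.724 Mb) rose by 0.60 ± 0.07 (adjusted p 1.1e-05), and across bins 50 and 44 by 0.31 ± 0.08 and 0.26 ± 0.07 (adjusted p 0.011 and 0.012). The rise at bin 66 rests on contacts of bin 65, since it was 0.08 (adjusted p 0.523) with bin 65 left out. Bins 60, 62 and 64, higher with an adjusted p of 0.041 each, also lost the call then (0.433, 0.260 and 0.817), and so did bins 6 and 24, which were lower (0.067 each). Within the whole left domain the change was -0.17 and did not pass (adjusted p 0.196), but it was -0.19 and passed as observed over expected (adjusted p 0.0063), where 9 blocks of the finer map passed.

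Single bin pairs of DCTCF4 changed mostly at bins 8, 70 and 4, and 4 pairs were higher and 19 lower among 2853, with 417 at an unadjusted p under 0.05. Bin 65 with bin 67, which spans bin 66, had a contact value of 469 ± 13.0 against 205 ± 42.4 in wild type (SD, n = 2 each), a log2 change of 1.19 ± 0.22 (SE, adjusted p 0.021). The other 3 higher pairs were bin 5 with bin 21 (0.80, adjusted p 0.0498) and bin 24 with bins 62 and 63 (0.72 each, adjusted p 0.021). Bin 24 with bins 62 and 63 holds 1 shared value. Of the 19 lower pairs, 8 involved bin 8 (28.485 to 28.506 Mb), 4 bin 70 (29.787 to 29.808 Mb) and 3 bin 4 (28.401 to 28.422 Mb). Bin 4 with bin 8 was at 37.2 ± 10.7 against 143 ± 2.26, a log2 change of -1.84 ± 0.23 (adjusted p 0.0030). Bin 35 with bin 50 was listed at 0 in both DCTCF4 libraries and at 20.9 ± 2.36 in wild type (adjusted p 0.012). The others named by the rule were bin 4 with bin 71 (-2.11), bin 4 with bin 67 (-1.74) and bin 70 with bin 77 (-1.55), with adjusted p from 0.0030 to 0.038.

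Insulation was higher at 8 and lower at 9 of 70 bins in DCTCF4, and 1 of 44 blocks passed, with 11 at an unadjusted p under 0.05. Against the wild type library of the same run year, the named bins changed by -0.41 (bin 5), -0.29 (bin 11), -0.22 (bin 7), 0.54 (bin 66), 0.23 (bin 50) and 0.23 (bin 44). The count of pairs was 103 without DCTCF4 replicate 1, 9 without DCTCF4 replicate 2 and 0 without wild type replicate 1, and 7 with the run year as a covariate. Called bins numbered 5, 10 and 3 without the same libraries, and called blocks 2, 4 and 0, with 2 blocks without wild type replicate 2. Without DCTCF4 replicate 1 bins 44 and 7 missed the threshold (adjusted p 0.145 and 0.074), without DCTCF4 replicate 2 bin 50 (0.129), and without wild type replicate 1 bins 50, 44 and 7 (0.185, 0.146 and 0.185), where bin 7 changed by -0.22. Bins 50 and 44 also missed it with a window of 3 bins (0.069 and 0.086), a window of 8 bins (0.051 and 0.599), the run year as a covariate (0.062 and 0.059) and the other deletion lines as control (0.069 and 0.080), and bin 7 with the run year (0.059). Of the 9 named pairs all missed it without wild type replicate 1 (adjusted p 0.056 to 0.252), all but bin 4 with bins 8 and 71 without DCTCF4 replicate 2 (0.069 to 0.167), and bin 5 with bin 21 and bin 70 with bin 77 without wild type replicate 2 (0.201 and 0.161).

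In DCTCF5 the right boundary was weaker. Contact across bins 63 (29.640 to 29.661 Mb), 64 (29.661 to 29.682 Mb) and 62 (29.619 to 29.640 Mb) rose by 0.42 ± 0.09, 0.42 ± 0.08 and 0.37 ± 0.07 (SE, n = 2 each, adjusted p 0.0019, 0.0015 and 0.0015). The rise ran without a gap from bin 60 (0.34, adjusted p 0.0015) to bin 66 (0.36, adjusted p 0.0015) and included the boundary bin 65 (0.32, adjusted p 0.020). The windows of these bins overlap, so the run is not independent support. The prominence at bin 65 was 0.86, against 1.31 in wild type. Contact fell across bins 33 (29.010 to 29.031 Mb), 12 (28.569 to 28.590 Mb) and 32 (28.989 to 29.010 Mb), by 0.36 ± 0.07, 0.24 ± 0.07 and 0.23 ± 0.07 (adjusted p 0.0015, 0.023 and 0.023).

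Insulation was higher at 7 and lower at 7 of 70 bins in DCTCF5, and all 7 higher bins lie at 60 to 66, where neighbouring windows overlap. With bin 65 left out, bins 13, 35 and 36 lost the call (adjusted p 0.067, 0.066 and 0.061), while bins 69 and 70 gained it (-0.25 and -0.23, adjusted p 0.014 and 0.032). Against the wild type library of the same run year, the named bins changed by 0.40, 0.40, 0.38, -0.42, -0.18 and -0.24 in the order above. The contact value between the central and the right domain was 9.31 ± 0.51 against 8.24 ± 0.28 (SD, n = 2 each), a log2 change of 0.18 ± 0.09 (SE) that did not pass (adjusted p 0.297). limma called 0 of 2853 bin pairs, with 152 at an unadjusted p under 0.05, and 0 of 44 blocks, with 2. The 3 pairs of smallest p were bin 4 with bin 7 (-1.11, adjusted p 0.122), bin 7 with bin 23 (-1.03, adjusted p 0.416) and bin 45 with bin 54 (-0.71, adjusted p 0.416). Without DCTCF5 replicate 1 there were 9 called pairs and without wild type replicate 1 there was 1. Bin 4 with bin 7 then passed in both cases (adjusted p 0.033 and 0.046), and bin 7 with bin 23 in the first (0.047). Called bins numbered 7 without wild type replicate 1 and 9 without wild type replicate 2, and 1 with a window of 3 bins. Bin 32 missed the threshold without DCTCF5 replicate 1 (-0.14, adjusted p 0.168), wild type replicate 1 (0.072) and wild type replicate 2 (0.109), and bin 12 without DCTCF5 replicate 2 (0.111) and wild type replicate 1 (0.189). With a window of 3 bins, bins 63, 62, 33, 12 and 32 missed it (0.129, 0.088, 0.080, 0.064 and 0.060). Bin 12 also missed it with a window of 8 bins (0.055), the other deletion lines as control (0.057) and the run year (0.096), and bin 32 with the run year (0.060).

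**Figure D2:**
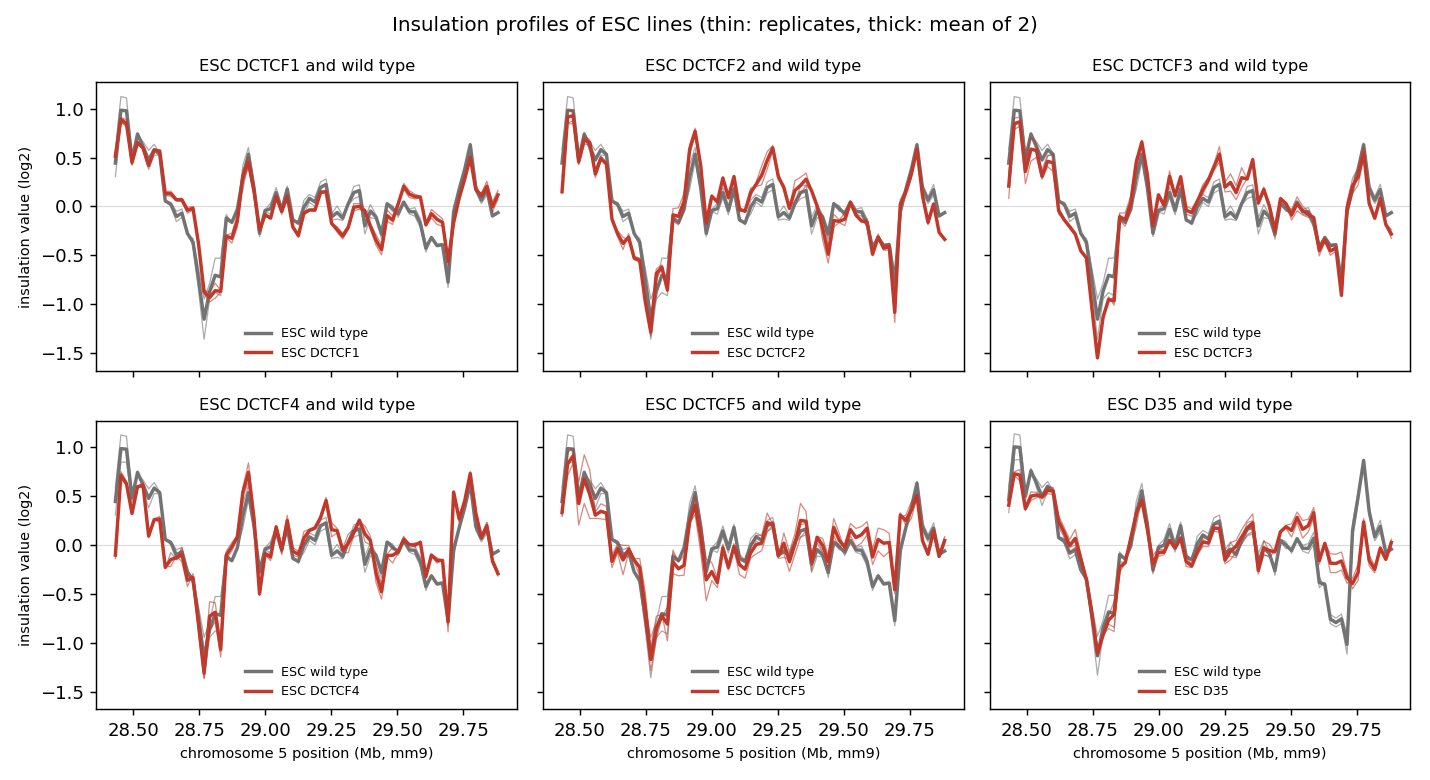
Insulation value (log2, y axis) along chromosome 5 (Mb, x axis) for each ESC deletion line in red and wild type in grey, with thin lines for the 2 replicates and thick lines for their mean, and with bin 65 left out in the D35 panel. DCTCF1 differs most at bins 19 and 20 (0.35 and 0.36), DCTCF5 at bins 63 and 64 (0.42 each), and D35 at bins 66 and 68 (0.68 and -0.77). With bin 66 also left out, the D35 change at bin 68 was -0.27.

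In D35 contact rose across the right boundary and contacts in the first bins of the right domain fell. Contact across bins 66 (29.703 to 29.724 Mb), 64 (29.661 to 29.682 Mb) and 65 (29.682 to 29.703 Mb) rose by 0.68 ± 0.08, 0.60 ± 0.09 and 0.59 ± 0.09 (SE, n = 2 each, adjusted p 2.7e-06, 2.1e-05 and 2.1e-05). Contact across bins 68 (29.745 to 29.766 Mb), 69 (29.766 to 29.787 Mb) and 67 (29.724 to 29.745 Mb) fell by 0.77 ± 0.08, 0.63 ± 0.07 and 0.54 ± 0.08 (adjusted p 4.0e-07, 1.0e-06 and 2.1e-05). The rise is not shown to be a weaker boundary, because the deletion also brings its 2 sides closer together. A block of contacts between the sides rose by 0.58 ± 0.08 (SE), of which the wild type decay over the shorter distance gives 0.33. The fall at bin 67 depends on contacts of bin 66, since it turned to 0.46 with bin 66 also left out. Bins 68 and 69 then changed by -0.27 each, no more than the distant bins 6 and 7 (-0.32 and -0.33). In the profiles without bin 65 the lowest value of this part lay at bin 67 in D35 (-0.39) and at bin 66 in wild type (-1.02). On the coarser map the contact value within the right domain was 35.9 ± 3.50 against 42.5 ± 2.34 in wild type (SD, n = 2 each), a log2 change of -0.24 ± 0.08 (SE, adjusted p 0.033). This block holds bin 66, and without its pairs, a check added after the data were seen, the change was -0.09 and did not pass (adjusted p 0.640).

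Bin 66 carried most of the losses among single pairs in D35, where 15 pairs were higher and 16 lower of 2778 tested, with 270 at an unadjusted p under 0.05. All 14 called pairs of bin 66 were lower, and of its 74 tested pairs 29 were higher and 45 lower, called or not. Bin 66 with bin 70 was at 9.49 ± 0.14 against 133 ± 35.7 in wild type (SD, n = 2 each), a log2 change of -3.27 ± 0.25 (SE, adjusted p 2.2e-05). Bin 66 with bins 74, 22, 4 and 78 changed by -1.98, -1.71, -1.50 and -1.38 (adjusted p 4.4e-04, 3.3e-05, 0.0069 and 0.0034). The highest rise was between bin 27 (28.884 to 28.905 Mb) and bin 44 (29.241 to 29.262 Mb), inside the central domain, at 131 ± 19.5 against 40.5 ± 4.35, a log2 change of 1.58 ± 0.21 (adjusted p 0.0020). Bins 6 and 7 (28.443 to 28.485 Mb) with bins 54 and 55 (29.451 to 29.493 Mb) hold 1 shared value, which rose by 1.56 ± 0.23 (adjusted p 0.0020).

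Insulation was higher at 10 and lower at 8 of 70 bins in D35, and 0 of 44 blocks passed by limma, with 8 at an unadjusted p under 0.05, while 6 passed with boundaries of prominence 0.1 and 3 as observed over expected. D35 was the only line of its run year, so its batch and its deletion cannot be told apart. Without pairs of bin 66, 14 pairs were higher and 1 lower, and with bin 66 also left out of the profiles bin 67 rose by 0.46 (adjusted p 3.7e-04) and the fall at bin 68 was -0.27 (adjusted p 0.017). In that profile bins 69 to 72 also fell (-0.27, -0.34, -0.20 and -0.27, adjusted p 0.0016 to 0.023), and so did the distant bins 6 and 7 (-0.32 and -0.33, adjusted p 0.017 and 0.0087). Counted once per distinct value, 5 pairs were higher and 16 lower. Called pairs numbered 18 without D35 replicate 1 and 20 without D35 replicate 2, and called bins 10 without D35 replicate 1 and 11 without wild type replicate 1. Bin 66 with bin 78 missed the threshold without D35 replicate 2 (adjusted p 0.054), and bin 4 with bin 66 without D35 replicate 1 (0.079), D35 replicate 2 (0.100) and wild type replicate 1 (0.101). The fall within the right domain had an adjusted p of 0.053 with the replicate block, 0.686 without D35 replicate 2 and 0.402 without wild type replicate 2. The central to right block passed without D35 replicate 1 (0.28, adjusted p 0.029).

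Between D35 and DCTCF5, tested directly on profiles without bin 65, contact across bin 68 was lower in D35 by a difference of -0.56 ± 0.08 (SE, adjusted p 4.4e-05). Bins 67, 69 and 70 were also lower in D35, with differences of -0.35, -0.38 and -0.27 (adjusted p 0.0057, 7.0e-04 and 0.013). The differences at bins 63 to 66 were from 0.23 to 0.26 and did not pass (adjusted p 0.058 to 0.085). 6 of 70 bins differed between these lines. With bin 66 also left out, a check added after the data were seen, no bin from 62 to 70 passed: the difference was 0.22 at bin 67, -0.21 at bin 68 (adjusted p 0.133 each), -0.10 at bin 69 (0.357) and -0.13 at bin 70 (0.282). The lower contact in D35 than in DCTCF5 thus depends on contacts of bin 66. Other pairs of lines were not compared directly, so a change called in 1 of them is not shown to be absent from the rest.

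**Figure D3:**
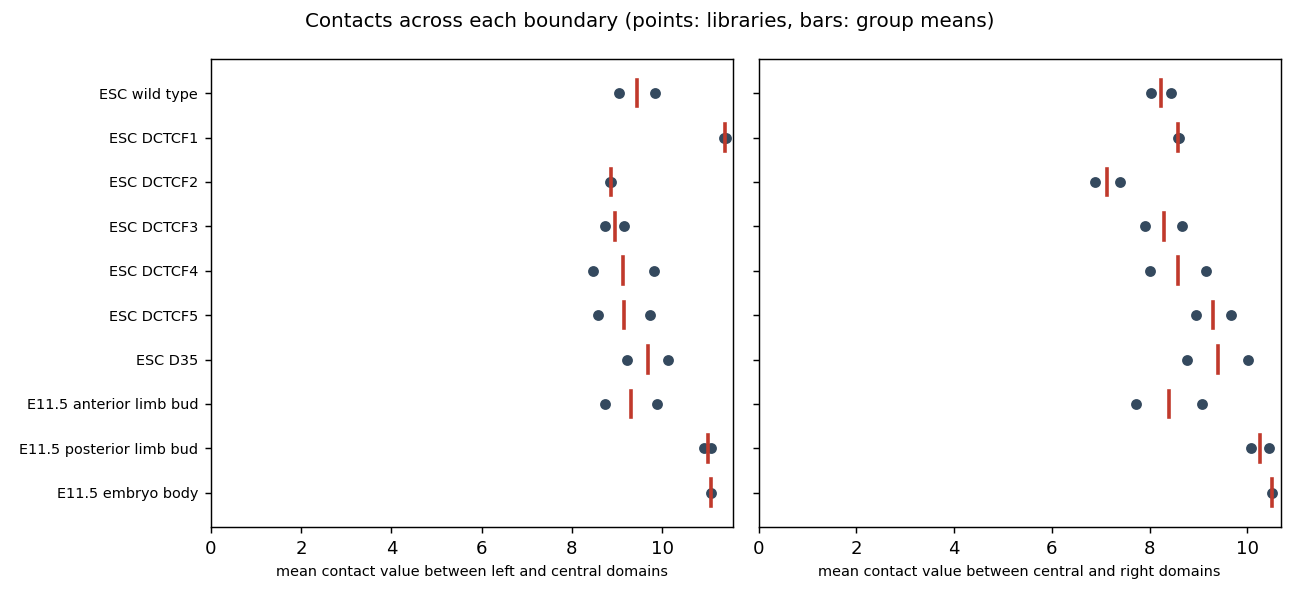
Mean contact value per library (x axis, no unit, starting at 0) between the left and central domains and between the central and right domains, with points for libraries and bars for group means. DCTCF1 has the highest left to central mean of the ESC lines, 11.4 against 9.45 in wild type, while D35 and DCTCF5 have central to right means of 9.40 and 9.31 against 8.24, which did not pass the test.

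The posterior part of the limb bud expresses Shh and the anterior part does not, as is known from general biology. The 3 bin pairs of smallest p were bin 8 with bin 23 (1.11), bin 67 with bin 77 (-1.11) and bin 16 with bin 65 (-0.85), posterior relative to anterior, and none passed (adjusted p 0.564 each). In the planned fit long-range blocks were higher in the posterior part, but no block passed when the sequencing day was included as a replicate block, a fit added after the data were seen. Contacts between 28.989 to 29.115 Mb and the right domain had a value of 9.03 ± 0.20 against 6.31 ± 0.91 in the anterior part (SD, n = 2 each), a log2 change of 0.53 ± 0.11 (SE, adjusted p 5.8e-04). Contacts within 28.779 to 28.968 Mb were 34.5 ± 3.12 against 43.3 ± 3.80, a log2 change of -0.33 ± 0.11 (adjusted p 0.028). With the replicate block both had an adjusted p of 0.108, at the same changes and with SE of 0.10 and 0.07. The fit without it used 1 spread for all blocks, and the fit with it leaves 1 residual degree of freedom, so the loss of the calls does not show that the sequencing day made the differences.

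Of 36 domain blocks, 9 were higher and 2 lower in the posterior part, and 0 passed with the replicate block, with 10 at an unadjusted p under 0.05. On the coarser map none passed, with smallest adjusted p of 0.074, or 0.083 with the replicate block. With boundaries from the anterior limb bud 2 blocks passed, and with those of prominence 0.1 a single one. The 9 higher blocks join separate domains, 5 of them across bin 21 and 4 across bin 65 or both, and the 2 lower ones lie within a domain. These calls go with a flatter decay of contact over distance, with slopes of -0.54 in both posterior libraries and of -0.64 and -0.72 in the anterior ones, and 0 blocks passed after each value was divided by the library's mean at its separation. No block passed without anterior replicate 2, posterior replicate 1 or posterior replicate 2, and 21 passed without anterior replicate 1. limma called 0 of 2853 bin pairs, with 214 at an unadjusted p under 0.05, and 0 of 70 insulation values, with 6. With the replicate block, which is also the sequencing day, the counts of pairs and of insulation values were 0 and 0, with smallest adjusted p of 0.158 and 0.053. Without posterior replicate 1, 15 pairs and 3 insulation values passed, and without posterior replicate 2, 3 pairs.

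Fragment counts showed no called contact between the parts with edgeR, 0 of 24533 pairs, with 1745 at an unadjusted p under 0.05. The smallest p belonged to Shh_140 (at 28.764 Mb) with Shh_198 (at 28.946 Mb), counted 93 and 102 times in the anterior libraries and 0 times in both posterior ones (adjusted p 0.639). DESeq2 called 7 higher and 9 lower pairs, at a setting where simulated counts gave 98 false calls. The replicate block called 3 lower pairs. Without posterior replicate 1, edgeR called 18 higher and 638 lower pairs. Total counts were 1022800 and 1383600 in the anterior and 749738 and 1400830 in the posterior libraries, and posterior replicate 2 had counts above 0 in 28.5 percent of pairs, against 34.1, 39.1 and 40.8 percent in the others. At the estimated dispersion of 1.11 edgeR recovered no simulated change of up to 3 on the log2 scale, so differences of that size may have been missed. Every simulated pair had the same dispersion, so real pairs with less spread are not covered. At a dispersion of 0.1, 55 of 66 changes of 3 were recovered.

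In D700 embryos the bins on either side of the deletion were in strong contact. Bin 26 (28.863 to 28.884 Mb) and bin 59 (29.556 to 29.577 Mb), which lie 693 kb apart on the reference and flank the missing 672 kb, had a contact value of 125 ± 2.67 (SD, n = 2) against 21.0 in the single embryo body library, a log2 change of 2.17 ± 0.19 (SE, adjusted p 0.0047). The pieces of the central domain left on both sides (28.779 to 28.884 Mb and 29.556 to 29.682 Mb) had a mean contact value of 50.8 ± 3.00 against 28.3, a log2 change of 0.84 ± 0.15 (adjusted p 2.0e-05). Contacts within the left piece were 57.1 ± 2.69 against 33.3, a log2 change of 0.78 ± 0.15 (adjusted p 4.3e-05). On the coarser map the left piece also had more contact with the right domain (0.37 ± 0.14, adjusted p 0.044). Every block of the coarser map had this SE of 0.14, from 4 bin pairs in the left piece to 294 between the left and the right domain. The p values therefore do not measure the spread of a small block, and the 2 blocks given before likewise share an SE of 0.15. The mean of all pairs across the junction changed by 0.07 ± 0.10.

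Of 993 bin pairs only bin 26 with bin 59 passed in D700, with 81 at an unadjusted p under 0.05, and 2 of 15 blocks passed. As observed over expected 0 bin pairs passed, and the block between the pieces of the central domain changed by -0.070 on the coarser map. Division by the mean at each separation removes part of that change by construction, and bin 26 with bin 59 has no such value. limma called 0 of 30 insulation values, with 1 at an unadjusted p under 0.05, bin 20 (0.36, adjusted p 0.680). Without scaling, the median change of D700 was 0.78 and 705 pairs passed, all of them higher, so the changes are relative to the total of the shared bins. Without D700 replicate 2 there were 2 called pairs and the block with the right domain had an adjusted p of 0.206, and without D700 replicate 1 there were 3 called insulation values, all lower. The body library and D700 come from different run years. Their titles also name different material, embryo bodies and D700 embryos. Run year, material and deletion therefore cannot be told apart.

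Wild type ESC and limb bud differed on the outer sides of both boundaries. Contact across bins 13 (28.590 to 28.611 Mb), 12 (28.569 to 28.590 Mb) and 11 (28.548 to 28.569 Mb) in the left domain was higher in ESC by 0.54, 0.53 and 0.48 (each ± 0.10 SE, n = 2 against 4, adjusted p 2.1e-06, 2.4e-06 and 1.9e-05). Contact across bins 67 (29.724 to 29.745 Mb), 68 (29.745 to 29.766 Mb) and 69 (29.766 to 29.787 Mb) in the right domain was lower in ESC, by -0.55, -0.53 and -0.49 (each ± 0.10 SE, adjusted p 2.1e-06, 2.4e-06 and 8.6e-06). The fit used the same spread for all bins, while the limb bud SD was 0.39, 0.37 and 0.31 at bins 67, 68 and 69. These p values therefore do not measure the spread at these bins. At bin 67 posterior replicate 2 was at 1.30, against 0.52 in posterior replicate 1 and 0.45 and 0.63 in the anterior libraries. Bin 8 (28.485 to 28.506 Mb) with bin 22 (28.779 to 28.800 Mb) had a contact value of 146 ± 70.2 in ESC and 24.2 ± 5.47 in limb bud (SD), a log2 change of 2.30 ± 0.26 (SE, adjusted p 0.044). Bin 23 (28.800 to 28.821 Mb) with bin 35 (29.052 to 29.073 Mb) was at 54.4 ± 10.9 against 14.5 ± 2.80, a log2 change of 1.59 ± 0.18 (adjusted p 0.044).

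Insulation was higher in ESC at 8 and lower at 8 of 70 bins, and 4 of 36 blocks were higher and 7 lower, while 21 passed as observed over expected. On the coarser map no block passed in the main fit, and the left and the right domain passed as observed over expected (0.19 and -0.37, adjusted p 0.0070 and 0.0014) and with the replicate block (0.22 and -0.26, adjusted p 0.024 and 0.016). The strongest block changes were 28.317 to 28.485 Mb with 28.779 to 28.968 Mb, higher in ESC (0.43 ± 0.09, adjusted p 0.0021), and 28.506 to 28.758 Mb with 29.304 to 29.430 Mb, lower (-0.42 ± 0.09, adjusted p 0.0022). Against the limb bud libraries of its own year, wild type replicate 1 gave 0.55, 0.58 and 0.57 at bins 13, 12 and 11 and -0.53, -0.51 and -0.51 at bins 67, 68 and 69. The 2 called pairs, among 404 of 2853 at an unadjusted p under 0.05, both missed the threshold with the replicate block (adjusted p 0.063 each) and without any 1 of anterior replicate 1 (0.196 each), anterior replicate 2 (0.282 each), posterior replicate 1 (0.065 and 0.057), posterior replicate 2 (0.167 each) and wild type replicate 1 (0.253 each), and bin 23 with bin 35 also without wild type replicate 2 (0.384). Without anterior replicate 1 bins 67, 68 and 69 missed it as well (adjusted p 0.074, 0.078 and 0.068), and without anterior replicate 2 too (0.082, 0.081 and 0.081). With a window of 3 bins, bins 67, 68 and 69 (adjusted p 0.174, 0.143 and 0.174) and bin 11 (0.28, adjusted p 0.092) missed it too. Called bins numbered 5 without either anterior replicate and 9 without either wild type replicate, and called blocks 5 without posterior replicate 1, 7 without posterior replicate 2 and 1 without wild type replicate 2. Cell type, genetic background (the E14 cell line, and CD1 mice per the labels) and tissue handling differ together between these groups.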

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

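Of 197 counts of changed features under another setting, 132 stayed within 1.5 times the count reported and 65 did not. Of 570 values of named bin pairs, 492 kept their direction and their side of the threshold, 68 lost the call and 10 gained it, and none turned. Of 400 values of named insulation bins, 306 kept both, 93 lost the call and 1 turned. Of 402 values on the coarser map, 372 kept both, 9 lost the call, 20 gained it and 1 turned. The cause was not tested for any of the changes below, unless a cause is named.

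The 2 values that turned are the D35 change at bin 67, which was 0.46 with bin 66 also left out, and the D700 change between the 2 pieces of the central domain, which was -0.070 as observed over expected. For the latter each value is divided by the mean at its separation, and the pieces make up most pairs at some separations, so part of the change is removed by construction. The pair bin 26 with bin 59 has no such value, because it is the only pair at its separation.

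Counts of changed bin pairs, higher and lower together, moved as follows. With the other deletion lines as control they were 31 (DCTCF1), 15 (DCTCF2), 10 (DCTCF3), 113 (DCTCF4), 30 (DCTCF5) and 140 (D35), where the control has more libraries. For DCTCF1 to DCTCF5 that control includes D35, and pairs of bin 65, read as lying in the D35 deletion, were kept. Such pairs can be called in a line that is itself unchanged there. The 15 of DCTCF2 do not include the pair reported above. In DCTCF2 the count was 0 with the pseudocount at the 1st percentile, 0 as observed over expected, 0 at separations of 5 bins or more, 0 with the authors' observed over expected and 0 with the run year as a covariate. In DCTCF4 it was 15 as observed over expected, 14 with the authors' observed over expected, 35 with the filter at the 25th percentile, 56 at separations of 1 bin or more and 7 with the run year. In D35 it was 15 without pairs of bin 66. With the spread shared over all full-size libraries it was 5 for the limb bud parts and 34 for wild type ESC against limb bud. In D700 it was 2 with the pseudocount at the 1st percentile, 705 without scaling, 0 as observed over expected, 2 at separations of 1 bin or more and 2 with scaling within the flanks. For wild type ESC against limb bud it was 0 with the pseudocount at the 25th percentile, 0 as observed over expected, 6 at separations of 1 bin or more, 0 at 5 bins or more and 0 with the replicate block.

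Counts of changed insulation values with a window of 3 bins were 0 (DCTCF1), 3 (DCTCF2), 5 (DCTCF3), 8 (DCTCF4), 1 (DCTCF5), 6 (D35) and 4 (wild type ESC against limb bud), and 8 with a window of 8 bins (DCTCF4). With each profile divided by its SD they were 2 (DCTCF1), 8 (DCTCF2), 1 (DCTCF3) and 2 (limb bud parts). With the other deletion lines as control they were 37 (DCTCF1), 42 (DCTCF2), 25 (DCTCF3), 25 (DCTCF5) and 31 (D35). For DCTCF1 to DCTCF5 the control again includes D35 with bin 65 kept, so windows that hold bin 65 are affected. With the replicate block the count was 14 in DCTCF3, although replicate numbers did not pair the ESC libraries. In DCTCF4 it was 6 with the run year and 11 with bin 65 left out.

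Counts of changed domain blocks with boundaries from the tested control were 5 (DCTCF1), 0 (DCTCF2), 1 (DCTCF3), 0 (DCTCF4) and 2 (limb bud parts). With boundaries of prominence 0.1 they were 0 (DCTCF4), 6 (D35) and 1 (limb bud parts). As observed over expected they were 1 (DCTCF3), 9 (DCTCF4), 3 (D35), 0 (limb bud parts) and 21 (wild type ESC against limb bud). With the replicate block, added after the data were seen, the count was 0 for the limb bud parts, against 11 reported. Fragment contacts called were 3 with the replicate block and 16 with DESeq2.

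Leaving out 1 replicate at a time, where the lone library is assumed to vary like the other groups, moved 59 of 112 counts. Changed bin pairs ranged from 0 to 0 (DCTCF1), 0 to 1 (DCTCF2), 0 to 0 (DCTCF3), 0 to 103 (DCTCF4), 0 to 9 (DCTCF5), 18 to 26 (D35), 0 to 15 (limb bud parts), 1 to 2 (D700) and 0 to 1 (wild type ESC against limb bud). Changed insulation values ranged from 0 to 3 (DCTCF1), 3 to 16 (DCTCF2), 0 to 17 (DCTCF3), 3 to 17 (DCTCF4), 7 to 19 (DCTCF5), 10 to 17 (D35), 0 to 3 (limb bud parts), 0 to 3 (D700) and 5 to 15 (wild type ESC against limb bud). Changed blocks ranged from 0 to 0 (DCTCF1), 0 to 4 (DCTCF2), 0 to 1 (DCTCF3), 0 to 4 (DCTCF4), 0 to 0 (DCTCF5), 0 to 0 (D35), 0 to 21 (limb bud parts), 2 to 2 (D700) and 1 to 10 (wild type ESC against limb bud), and fragment contacts from 0 to 656.

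The correlation within ESC lines stayed above that between lines with Spearman correlation (0.837 against 0.767) and without removal of the mean at each separation (0.929 against 0.891), with a permutation p of 2e-05 each. The planned test of fixed pairs of promoters and enhancer was not run. No simulated change of fragment counts was recovered by edgeR at their dispersion, and counts thinned to the smallest library gave 0 called contacts.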

Other observations

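The tests of the other sequencing batch of D35, of the shared wild type libraries and of the run year were chosen only after their results were seen, and the test of the D700 distance was written down when the change of the block was already known.

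In D35 insulation was higher at bins 64 to 66 and lower at bins 67 to 69 than in wild type ESC. Loss of contacts of bin 66, which may lie partly in the deletion, stays open: with bins 65 and 66 left out the fall at bin 68 was -0.27 (SE 0.08, adjusted p 0.017), smaller than the -0.77 reported. Of the 74 tested pairs of bin 66, 29 were higher and 45 lower. A batch effect also stays open, as the largest change at bins at least 15 bins away from bin 65 was 0.28 (SE 0.08). With bins 65 and 66 left out, the distant bins 6 and 7 fell by 0.32 and 0.33, so the fall left at bin 68 is no larger than theirs, while bins 69 to 72 fell by 0.20 to 0.34. The shorter distance across the deletion stays open too. Contacts between bins 60 to 63 and bins 67 to 71 rose by 0.58, where the wild type decay for 2 bins less gives 0.33. The excess was 0.25 (SE 0.08), and its SE holds no error of the expected value. As a change of a block of contact values, the excess is not comparable in size with the insulation changes at distant bins. Contact also decayed less steeply in D35, with a mean slope of -0.62 against -0.70 in wild type. No called bin pair links the 2 sets of bins. The insulation rise at bin 64 does not depend on bin 66, since it was 0.74 without it. An effect of the deletion on the right boundary is a hypothesis that was not tested here, because D35 shares its run year with no other line.

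In D700 contacts between the 2 remaining pieces of the central domain were higher. Shorter distance stays open: the block rose by 0.84 where the decay of the embryo body gives 1.57, a difference of -0.73 (SE 0.11), and the test was one-sided, so that any rise below 1.57 would have been allowed. Contacts within the pieces, whose distances did not change, differed by 0.78 in the left one (4 bin pairs, adjusted p 2.4e-05) and by 0.18 in the right one (6 bin pairs, adjusted p 0.435, not passed), against a single body library. Both blocks were given the same SE as larger blocks, which does not measure the spread of so few pairs. The scaling of matrices with few long separations also stays open. With scaling on pairs within either flank the change was 0.86 (SE 0.10). The mean of all pairs across the junction changed by only 0.07, so leaving them out of the scaling could hardly move the block. Run year, the material named in the titles (embryo bodies or D700 embryos) and deletion cannot be told apart here. An effect of the deletion beyond distance was not tested.

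Contact was higher across bins 43 to 45 and 49 to 50 in DCTCF2, DCTCF3 and DCTCF4, by 0.32, 0.30 and 0.24 against wild type. These bins were picked because they are high in the same libraries, so tests on them cannot decide, and both explanations tested stay open. For chance values of the 2 shared wild type libraries, the mean change against the other deletion lines was at least 0.13 (SE 0.04, DCTCF4) and at most 0.23. For the run year, the change with it as a covariate was at least 0.20 (SE 0.06, DCTCF4) and at most 0.36. The changes of the whole profiles correlated at 0.75 (DCTCF2 with DCTCF3), 0.59 (DCTCF2 with DCTCF4) and 0.56 (DCTCF3 with DCTCF4), where a shared wild type alone gave 0.49 in simulations. Their covariances, which keep the size of the changes, were 0.023, 0.018 and 0.015 in the same order, against 0.0036 in the simulations. Simulated bins were drawn independently, while the windows of real bins overlap. Other pairs of lines ran from -0.51 (DCTCF1 with DCTCF2) to 0.76 (DCTCF5 with D35), with covariances of -0.015 and 0.030. Apart from DCTCF5 with D35, their correlations were at most 0.51 (DCTCF1 with D35, covariance 0.019). High values are thus not limited to the 3 lines, but few other pairs reach them. An effect of the deletions and differences between clones were not tested.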
